A study of Mus musculus with 6 samples.

How the data were processed

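Total RNA from the livers of 6 male mice aged 3 weeks was labelled with biotin by the Affymetrix one-cycle procedure, per the labels' protocols, and each sample was hybridised to 1 array. The 3 control mice carried 1 loxP-flanked and 1 normal copy of Srf together with the AlfpCre transgene, and the 3 mutant mice carried 2 loxP-flanked copies with the same transgene. Samples were grouped by their titles, and the design text calls the mice separate animals. No batch, slide or scan date is given in the sources used here.

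The deposited table held 1 linear intensity per probe set and array, a brightness value on a linear scale. Per the submitters' processing notes the signals came from GCOS, the Affymetrix scanner software; the algorithm, version and scaling target are not given in the sources used here. No detection calls were used here. The table had 45101 probe sets, of which 64 were array controls. Of the others, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there. Symbols were updated through the Entrez identifier for 34741 probe sets, and 204 kept the annotation symbol. Probe sets with several symbols were not assigned to a gene. No genome build is named, so no coordinates are given.

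The mean deposited signal after trimming 2% of probe sets at each end was 55.2, 69.9 and 60.8 on control arrays 1 to 3 and 37.3, 58.1 and 42.5 on mutant arrays 1 to 3. These means differed by more than the 5% set as the limit for keeping the deposited scaling, so each array was multiplied to the mean of the 6 trimmed means. Signals under 1 were then set to 1, which applied to between 12.4% and 17.1% of probe sets per array, and log2 was taken. The lower 40% of probe sets by mean log2 signal over all 6 arrays were left out, a threshold of 2.10, and 27022 probe sets were kept. A gene was represented by its kept probe set with the highest mean signal among those with 1 symbol, giving 13144 genes. Of these, 5871 had more than 1 kept probe set. Among called genes only Cyp51 had another kept probe set past the threshold, in the same direction. The check for opposite directions thus had little to test. Because the scaling sets the arrays' trimmed means equal, a change shared by most transcripts would not show.

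Mutant and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a trend in the variance prior. The test was two-sided, with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. Background was estimated from 83 probe sets of olfactory, vomeronasal and bitter taste receptors, genes assumed not to be expressed in liver. The 95th percentile of their mean log2 signals was 2.87 in controls and 3.04 in mutants. Where a group mean lay at or below that level, the fold is given as a lower bound against it. The bound uses the mean of the 3 arrays and is not strict where an array of that group lay above the level. With 3 arrays per group, the number of arrays limits the precision.

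Gene lists were written before the data were examined, 42 in all, from textbook knowledge of liver, of targets of the transcription factor SRF and of other cell types found in liver. The 41 lists with at least 5 genes kept were tested with camera, with a preset correlation of 0.01 between genes, and adjusted over the lists. The mean of a list uses fitted values, which are no exact size for members with a group below background, so it was also computed with such group means raised to the background estimate. Members were also counted after adjustment over all probe sets and adjusted over the list alone. The test was repeated with camera's estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes. The growth hormone, cyclin, cytochrome P450 and metabolism lists cover classes that the labels mention, so their direction is not independent evidence.

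Named genes followed a rule set before the data were examined. It takes Srf, up to 12 of the largest rises and up to 12 of the largest falls past the threshold with separated groups, and up to 4 members with the smallest adjusted p of each list described. Genes named outside it are marked as such. Probe sets ending in x_at or s_at can detect related transcripts and are marked as shared.

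RNA quality was followed by the ratio of the 3' to the 5' control probe sets of Actb, Gapdh and Pcx, compared by a two-sided exact permutation test. The sex given in the labels was checked on the arrays. The Y-linked gene Eif2s3y (1417210_at) gave log2 signals between 7.37 and 8.52 on the 6 arrays, and the X-inactivation transcript Xist was at 0 on each (1427262_at), at most 1.62 (1427263_at) and between 1.68 and 3.25 (1436936_s_at, highest in mutant 1).

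The steps were tested on simulated data. With 200 of 27022 probe sets changed and noise of the measured spread, the limma step recovered 0% of changes of 1 on the log2 scale, 16.4% of changes of 2 and 54.5% of changes of 4, with 2 false calls. With a lower noise it recovered 58.2%, 83.6% and 100% of those sizes, with 11 false calls. The list step, run on 13144 genes with 1 list shifted by -1, returned that list with an adjusted p of 3.78e-19 and called 0 others. Its simulated noise was independent between genes, so it did not test lists whose genes vary together.

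Before the data were examined, 12 alternatives were listed, on normalization, offset, filter, variance prior, a replicate block, leaving out each array, a fold threshold, the summary of a gene's probe sets and the list test. A further 4 were chosen after seeing the data: the deposited scaling, the 3' over 5' index (mean log2 ratio of Gapdh and Pcx) as a covariate, limma array weights, and the comparison of mutant 2 alone with the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.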

Results

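Gene expression was measured on arrays in the livers of male mice aged 3 weeks, 3 controls and 3 mutants. SRF is a transcription factor that drives actin cytoskeleton and immediate early genes. The mutants carried loxP sites in both copies of Srf together with Cre recombinase from the AlfpCre transgene, and the controls carried them in 1 copy with the same transgene. The comparison asks which liver transcripts differ when both copies of Srf are targeted. Pearson correlations of log2 signal across probe sets were 0.937 to 0.941 between controls, 0.827 to 0.907 between mutants and 0.781 to 0.931 between the groups. The first principal component held 50.3% of the variance, with scores of -77.5, -69.8 and -50.6 for the controls and 177, -22.8 and 43.9 for mutants 1 to 3.

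The Srf transcript itself did not pass the test. Its brighter probe set (1418256_at) gave log2 signals of 5.31, 5.14 and 5.11 on the control arrays and 4.17, 5.24 and 2.54 on the arrays labelled mutant 1, mutant 2 and mutant 3. The log2 fold change was -1.20 (SE 0.62, adjusted p = 0.398, limma). The shared probe set 1418255_s_at was dim, at 3.00, 3.69 and 3.37 in controls and 3.29, 0 and 1.99 in mutants (adjusted p = 0.411), and its mutant mean of 1.76 lay below the background estimate. The array labelled mutant 2 thus lay within the control range on 1 probe set and at the floor on the other. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, so they do not check the labels.

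The control probe sets for RNA quality differed between the arrays. The 3' to 5' ratio of Pcx was 4.94, 4.44 and 7.03 in controls and 17.3, 6.39 and 10.5 in mutants 1 to 3 (exact permutation p = 0.2). For Gapdh the means were 0.715 ± 0.0383 and 0.882 ± 0.117 (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). For Actb the ratio was 1.91, 1.68 and 2.36 in controls and 5.33, 2.36 and 2.92 in mutants (exact permutation p = 0.2). Mutant 2 was the mutant array closest to the controls in each of the 3 ratios.

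**Figure D1:**
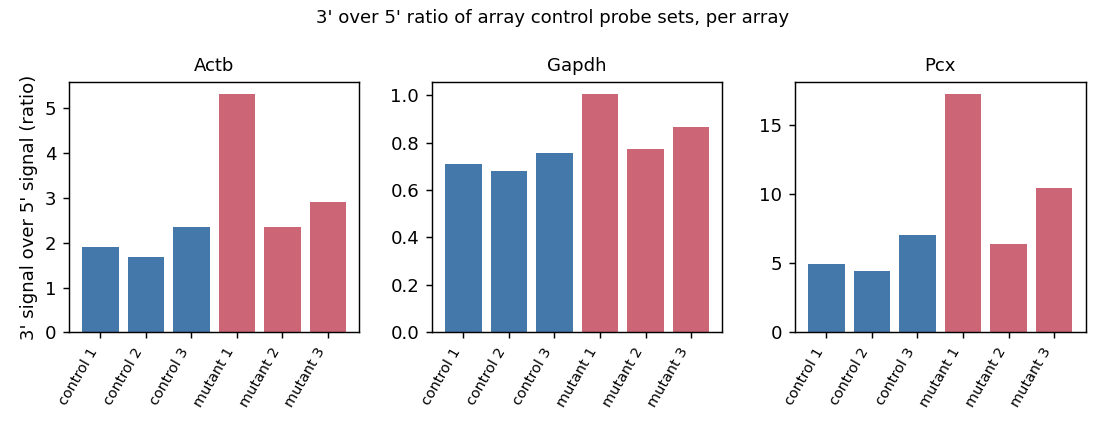
Ratio of the 3' signal to the 5' signal (vertical axis, no unit) for the Actb, Gapdh and Pcx control probe sets, 1 bar per array, controls in blue and mutants in red. Mutant 1 has the highest bar in each panel, 17.3 for Pcx, and the Gapdh bars of all 3 mutants lie above those of the controls.

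In mutant liver 4 genes rose. Sult1e1 (1420447_at) encodes estrogen sulfotransferase. Its mean log2 signal went from 2.03 ± 0.99 in controls to 9.72 ± 1.16 in mutants (SD, n = 3). The mutant mean was 116-fold above the control background estimate, which control 3 slightly exceeded at 2.96 (fitted log2 difference 7.69, SE 0.67, adjusted p = 0.0129). S100g (1448964_at), a calcium-binding protein, rose at least 15.9-fold and Wif1 (1425425_a_at), a secreted inhibitor of Wnt ligands, at least 7.85-fold (adjusted p = 0.0216 and 0.0363). All 3 of these had a control mean below the background estimate. Abcc4 (1443870_at), an efflux transporter of the cell membrane, rose by 2.69 on the log2 scale (SE 0.29, adjusted p = 0.0363), 6.46-fold.

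The 11 genes that fell included enzymes of sterol and drug metabolism. The largest of these falls was in Mup3 (1427631_x_at, shared), a major urinary protein made by liver, from 12.18 ± 0.69 to 3.41 ± 0.87 (SD, n = 3), a log2 fold change of -8.77 (SE 0.50, adjusted p = 0.00208). Cyp2c54 (1455457_at), a cytochrome P450, changed by -6.29 (SE 0.42, adjusted p = 0.00333) and Cyp2c23 (1424576_s_at, shared) by -3.45 (adjusted p = 0.0418). In cholesterol synthesis, Sqle (1415993_at), squalene epoxidase, changed by -5.05 (SE 0.37, adjusted p = 0.00533) and Cyp51 (1450646_at), lanosterol demethylase, by -3.96 (adjusted p = 0.0458). Cdc20 (1439377_x_at, shared), an activator of the anaphase-promoting complex, changed by -3.52 (adjusted p = 0.0251). Ugt2a3 (1450133_at), a glucuronosyltransferase, changed by -2.48, and Ang (1438936_s_at, shared), the ribonuclease angiogenin, by -2.56 (adjusted p = 0.0216 and 0.0363). The water channel Aqp8 (1417828_at) changed by -3.43 (adjusted p = 0.0425). Gm2788 (1448080_at) was at least 9.63-fold lower and Fitm1 (1451488_at), which acts in lipid droplet formation, at least 9.45-fold lower. In each of the 15 genes all 3 mutant arrays lay beyond all 3 controls.

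**Figure D2:**
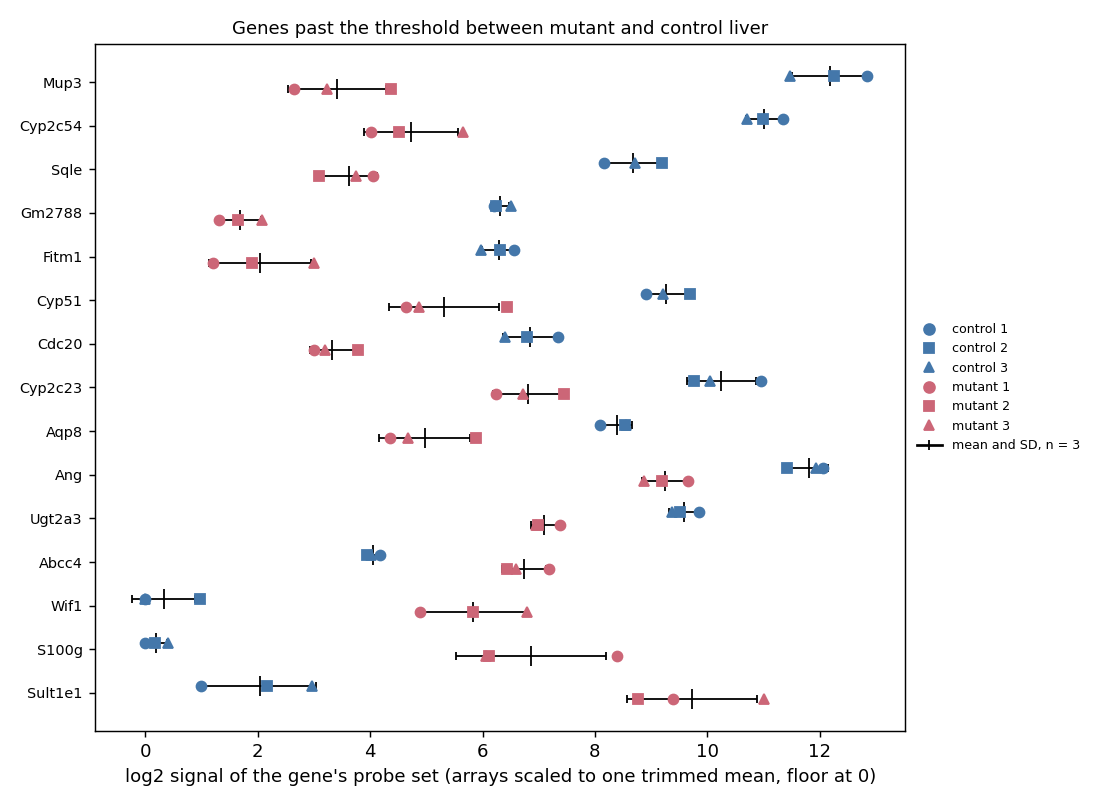
log2 signal (horizontal axis) of the 15 genes past the threshold, with 1 point per array, controls in blue, mutants in red, marker shape for the replicate number, and a black bar for the mean and SD of 3 arrays. Mup3 lies between 11.47 and 12.83 in controls and between 2.64 and 4.36 in mutants, and no control point overlaps the mutant points of any gene.

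By probe set, 4 were higher and 16 lower. Beside the 15 genes these were another probe set of Cyp51, 1 of Nrep and 3 without a single gene symbol. That of Nrep (1450839_at) had a mean log2 signal of 8.60 in controls and 2.20, 4.01 and 2.91 in mutants 1 to 3 (adjusted p = 0.0214, limma). The brighter probe set of Nrep did not pass (-4.45, adjusted p = 0.0757). Without a single symbol, 1451600_s_at is listed for the carboxylesterases Ces3a and Ces3b. Its mean log2 signal was 11.95 in controls, with 0, 5.14 and 1.82 in mutants 1 to 3 (adjusted p = 0.0395, limma). Mutant 2 lay above the background estimate on the Nrep probe set and on 1451600_s_at, so no lower bound is given. The probe sets 1434110_x_at and 1418281_at are not in the platform annotation. These were named after their values were seen. At an unadjusted p under 0.05, 967 genes were higher and 922 lower. The groups were separated for 3272 genes, 24.9% of those kept, where 10% is the average expected by chance. Genes on the same arrays vary together, so the share in a single grouping can lie far from 10% by chance. It was not computed for other groupings. The number of genes past the threshold depended on the setting: it was 0 without the filter on dim probe sets (limma; 1250 higher and 920 lower at an unadjusted p under 0.05), 5 without the variance trend, 67 after log2(signal + 32) and 3 with the 3' over 5' index as a covariate. Without control 1, 2 or 3 it was 3, 1 and 3, and without mutant 1, 2 or 3 it was 83, 310 and 7. On the deposited scaling 3 genes were higher and 18 lower, and 192 higher and 1818 lower at an unadjusted p under 0.05, with the median of all genes at -0.39 in place of 0.06. All 15 genes kept their direction in each setting that tested them.

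Genes of S phase and mitosis were lower as a list in mutant liver. Their mean log2 fold change was -1.88 over 42 genes, 41 of them negative, with array shifts of -1.93, -1.50 and -2.21 in mutants 1 to 3 against a control SD of 0.31 (camera adjusted p = 1.51e-21; adjusted p = 0.573 with an estimated correlation). For 21 of the 42 a group mean lay below background, and with these raised to it the mean was -1.44. Over all probe sets 1 member fell, Cdc20, and 30 were lower adjusted over the list alone. Mad2l1, a spindle checkpoint protein, had a log2 fold change of -2.70 (SE 0.40, adjusted p = 0.0757), and the chromosomal passenger protein Birc5, below background in the mutants, was at least 6.46-fold lower without passing (adjusted p = 0.127). A separate list of cyclins and cyclin-dependent kinases did not pass (mean -0.30 over 31 genes, camera adjusted p = 0.134). It also holds kinase inhibitors such as Cdkn1a, so its test of direction does not speak for the mitotic members alone. The 4 members lower adjusted over the list alone were Ccna2, Ccnb2, Ccnd1 and Cdk1. The mitotic cyclin Ccna2 had -2.38 (adjusted p = 0.0875). The mean of the S phase and mitosis list was -1.48 with the 3' over 5' index as a covariate (camera adjusted p = 1.84e-21).

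Cholesterol synthesis genes were lower as a list, with a mean log2 fold change of -2.61 over 20 genes, of which 19 were negative. The shifts were -3.32, -1.73 and -2.79 in mutants 1 to 3 against a control SD of 0.23 (camera adjusted p = 1.51e-21; adjusted p = 0.616 with an estimated correlation). Sqle and Cyp51 passed over all probe sets and 19 were lower adjusted over the list alone. Hmgcs1, the cytosolic synthase upstream of HMG-CoA reductase, had -2.70 (SE 0.35, adjusted p = 0.0642) and Tm7sf2, a sterol reductase, -2.74 (adjusted p = 0.0757). The list of fatty acid and triglyceride synthesis was also lower (mean -1.33 over 26 genes, camera adjusted p = 1.42e-05; adjusted p = 0.707 with an estimated correlation). None of its members passed over all probe sets, while 9 were lower and 2 higher adjusted over the list alone; ATP citrate lyase, Acly, had -2.03 (adjusted p = 0.133). With the 3' over 5' index as a covariate the cholesterol list kept a mean of -1.70 (camera adjusted p = 1.01e-23), and the fatty acid list had -0.28 (camera adjusted p = 0.160).

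Genes that are more abundant in male than in female adult mouse liver were lower as a list in the mutants, which like the controls were male. The mean log2 fold change was -3.16 over 19 genes, 17 of them negative (camera adjusted p = 5.50e-12; adjusted p = 0.621 with an estimated correlation). For 7 of the 19 a group mean lay below background, and with these raised to it the mean was -2.62. The controls themselves spread over this list, at 0.93, 0.12 and -1.04 around their mean, and the mutants lay at -3.74, -2.67 and -3.07. Mup3 passed over all probe sets and 13 members were lower adjusted over the list alone, among them the nudix hydrolase Nudt7 at -3.20 (adjusted p = 0.0757) and the P450 Cyp4a12a, below background in the mutants and at least 21.3-fold lower (adjusted p = 0.0933). The major urinary protein list had 3 genes kept, too few for the test, with a fitted mean of -5.82, or -4.97 with the 2 genes below background raised to it; Mup10, below background in the mutants, was at least 14.6-fold lower without passing (adjusted p = 0.0757). The female-biased list did not pass (mean 0.41 over 19 genes, camera adjusted p = 0.134), with 1 member higher over all probe sets, Abcc4, and 3 higher adjusted over the list alone. With the 3' over 5' index as a covariate the male-biased list kept a mean of -2.14 (camera adjusted p = 3.13e-12) and the female-biased list had 1.22 (camera adjusted p = 0.000272).

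Cytochrome P450 genes of drug metabolism went both ways. The list did not pass (mean -0.84 over 36 genes, camera adjusted p = 0.0596), with 2 lower over all probe sets, Cyp2c54 and Cyp2c23, and 12 lower and 4 higher adjusted over the list alone. Cyp2f2 had -4.53 (SE 0.69, adjusted p = 0.0757). The list of phase II conjugation and transport was lower (mean -0.63 over 34 genes, camera adjusted p = 0.0113; adjusted p = 0.707 with an estimated correlation), with Ugt2a3 lower and Abcc4 higher over all probe sets, and 6 lower and 3 higher adjusted over the list alone. Its shifts were -1.49, -0.05 and -0.34 in mutants 1 to 3, and the call was lost without mutant 1 (adjusted p = 0.781) and on the deposited scaling (adjusted p = 0.0947). With the 3' over 5' index as a covariate its mean was 0.23 (camera adjusted p = 0.0916), and that of the P450 list was -0.35 (camera adjusted p = 0.160).

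The growth hormone and IGF1 axis did not pass as a list (mean -0.14 over 19 genes, camera adjusted p = 0.874). None of its members passed over all probe sets, while 4 were lower and 4 higher adjusted over the list alone. Igf1, the growth factor that liver secretes in response to growth hormone, had a log2 fold change of -2.89 (SE 0.44, adjusted p = 0.0757), with 11.19 ± 0.47 in controls and 8.30 ± 0.84 in mutants (SD, n = 3). Igfals and Igfbp3, which carry IGF1 in serum, had -4.14 (adjusted p = 0.0894) and -1.73 (adjusted p = 0.0888), and the binding protein Igfbp1 had 1.62 (adjusted p = 0.0888). The labels mention this axis, so the direction of these genes is not independent evidence.

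Both lists of SRF targets passed, in opposite directions. Actin cytoskeleton targets were lower (mean -0.44 over 39 genes, 31 negative, camera adjusted p = 0.00259; adjusted p = 0.707 with an estimated correlation), with shifts of -0.58, -0.02 and -0.73 in mutants 1 to 3. None of them passed over all probe sets or adjusted over the list alone; Actb had -1.05 (SE 0.22, adjusted p = 0.182), the focal adhesion protein Vcl -0.90 (adjusted p = 0.326) and Tagln2 1.11 (adjusted p = 0.343). Without mutant 3 the call was lost (adjusted p = 0.106). Immediate early targets were higher (mean 1.07 over 23 genes, 22 positive, camera adjusted p = 3.65e-05; adjusted p = 0.624 with an estimated correlation), with shifts of 1.75, 0.60 and 0.84. The orphan receptor Nr4a1, at 2.17 (SE 0.44, adjusted p = 0.164), was the 1 member higher adjusted over the list alone. Neither call remained with the 3' over 5' index as a covariate, with means of -0.13 and 0.37 (camera adjusted p = 0.160 for both).

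Interferon-stimulated genes were lower as a list (mean -1.18 over 28 genes, 27 negative, camera adjusted p = 4.37e-11; adjusted p = 0.624 with an estimated correlation), with shifts of -1.15, -0.49 and -1.92 in mutants 1 to 3. With the group means of 5 members raised to background the mean was -1.04. None passed over all probe sets and 10 were lower adjusted over the list alone, among them the GTPase Igtp at -1.63 (adjusted p = 0.189) and Ifit1 at -1.49 (adjusted p = 0.193). Markers of hepatic stellate cells and myofibroblasts were lower (mean -0.55 over 44 genes, 34 negative and 10 positive, camera adjusted p = 0.00098, and 0.707 with an estimated correlation). No member passed either adjustment. Pdgfra, with the smallest adjusted p of the list, had 1.28 (adjusted p = 0.277), and Col3a1, a fibrillar collagen, had -3.56 (adjusted p = 0.296). The shifts of the stellate list were -1.33, 0.24 and -0.56 in mutants 1 to 3, and the call was lost without mutant 1 (adjusted p = 0.0694). With the 3' over 5' index as a covariate the interferon list had a mean of -0.75 (camera adjusted p = 1.17e-06) and the stellate list 0.28 (camera adjusted p = 0.160).

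Cytosolic ribosomal protein genes were higher as a list, with 36 of 36 genes positive and a mean of 0.73 (camera adjusted p = 6.88e-09; adjusted p = 0.707 with an estimated correlation). Their shifts were 1.46, 0.10 and 0.63 in mutants 1 to 3, and no member passed either adjustment. Adding the 3' over 5' index as a covariate gave a mean of -0.04 (camera adjusted p = 0.146). Oxidative phosphorylation genes were higher (mean 0.19 over 56 genes, camera adjusted p = 0.0162; adjusted p = 0.707 with an estimated correlation), with no member past either adjustment. That call was lost without control 2 (adjusted p = 0.111), after quantile normalization (adjusted p = 0.363) and on the deposited scaling (adjusted p = 0.852). Acute phase genes were higher (mean 0.55 over 28 genes, camera adjusted p = 0.0484; adjusted p = 0.707 with an estimated correlation), with shifts of 1.69, 0.17 and -0.22. Of them 3 were higher and 1 lower adjusted over the list alone, including the metallothionein Mt1 at 2.99 (adjusted p = 0.191); the call was lost without control 2, mutant 1 or mutant 2 (adjusted p = 0.147, 0.826 and 0.0544). It was also lost after quantile normalization (adjusted p = 0.209), with arrays centred on their median (0.0558), without the filter on dim probe sets (0.0625) and with the mean over a gene's probe sets (0.0552). Among 20 alternative settings, counting each array left out, 8 kept the acute phase call. With the index as a covariate the means were 0.08 for oxidative phosphorylation and -0.44 for acute phase genes, and neither passed.

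**Figure D3:**
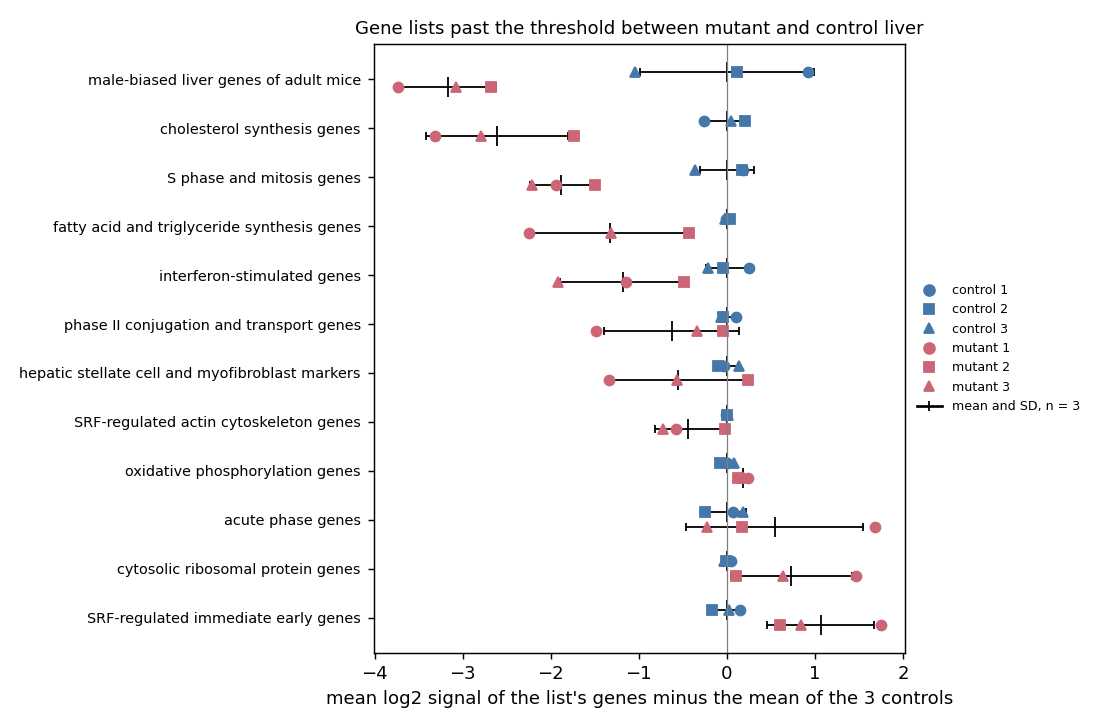
Mean log2 signal of each list's genes relative to the mean of the 3 controls (horizontal axis) for the 12 lists past the threshold, with 1 point per array, controls in blue, mutants in red, and a black bar for the mean and SD of 3 arrays. Mutant 2 lies nearer 0 than mutants 1 and 3 for cholesterol synthesis (-1.73 against -3.32 and -2.79), and acute phase genes are highest in mutant 1 (1.69).

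Of the 41 lists, 8 were lower and 4 higher by camera with the preset correlation. All 3 mutant arrays lay beyond all controls for 9 of these 12, and for 16 of all 41. The 12 were called on the same difference, which partly builds this separation in. With an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.0679; 11 at an unadjusted p under 0.05). Regrouping the 6 arrays in the 9 other ways gave between 8 and 18 lists by the same test with the preset correlation.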

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

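The deposited scaling, the 3' over 5' covariate, array weights and mutant 2 alone were chosen after seeing the data. Genes higher numbered 4: 0 without the filter, 2 with the lower 60% left out, 0 without the variance trend (803 at an unadjusted p under 0.05), 2 with the replicate block, 0 with the covariate (286), 758 with array weights, 10 with mutant 2 alone and 0 to 74 leaving out 1 array. Genes lower numbered 11: 19 with arrays centred on their median, 62 after log2(signal + 32), 0 without the filter (920), 7 with the lower 60% left out, 5 without the trend, 18 on the deposited scaling, 3 with the covariate, 894 with array weights, 96 with mutant 2 alone and 1 to 236 leaving out 1 array. Array weights come from the same 6 arrays and were 0.20, 0.46 and 2.92 for mutants 1 to 3. The weighted counts thus rest largely on mutant 3. Mutant 2 alone is assumed to vary like the controls. The replicate block changed no other count by over 1.5 times. After each group's mean was subtracted, same-numbered arrays correlated at -0.04, 0.02 and 0.04. This gives no sign that the numbers pair the mice, but cannot exclude it.

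Lists higher numbered 4: 2 after quantile normalization, 0 with an estimated correlation, 0 with fry, 7 with mutant 2 alone and 2 to 5 leaving out 1 array (2 without control 2). Lists lower numbered 8: 0 with an estimated correlation, 0 with fry, 5 with the covariate and 7 to 11 leaving out 1 array. Apart from the estimated correlation and fry, the S phase, cholesterol, male-biased and interferon lists kept their calls in every setting run. For lists past the threshold in the main fit or in the alternative, the direction of the test reversed at a mean shift from the median of all genes of -0.45 for plasma proteins after quantile normalization and 0.13 for oxidative phosphorylation on the deposited scaling; in both the test alone turned. With the covariate they were 0.14 for phase II, 0.20 for stellate, 0.53 for endothelial, -0.52 for acute phase, 0.32 for pericentral and -0.12 for ribosomal protein genes. With mutant 2 alone they were -0.11 for phase II, where the test alone turned, 0.18 for stellate, 0.60 for endothelial and 0.19 for pericentral genes. Srf stayed negative except with mutant 2 alone (0.05) and ranged from -1.83 to -0.48 leaving out 1 array. It passed with array weights (-2.21, adjusted p = 0.0214, limma), where the largest weight fell on mutant 3, the array with the lowest signal on that probe set. The adjusted p of Srf ranged elsewhere up to 0.981. The cause of these changes between settings was not tested. For 5 of the 15 genes 1 group lies below background, which limits their folds.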

Other observations

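Among lists not described so far, none of the following passed the camera test. In hepatocyte metabolism the mean log2 fold change was -0.58 for bile acid synthesis and transport (adjusted p = 0.104), 0.22 for fatty acid oxidation and ketogenesis (adjusted p = 0.467), -0.26 for gluconeogenesis and glycogen (adjusted p = 0.739), -0.08 for urea cycle and amino acid catabolism (adjusted p = 0.313) and -0.22 for plasma proteins (adjusted p = 0.625). The urea cycle, plasma protein and periportal lists had a negative mean but a positive median and test direction. Periportal genes had a mean of -0.21 (adjusted p = 0.780) and pericentral genes -0.39 (adjusted p = 0.522). Adjusted over the list alone, 4 urea cycle genes were higher, including Ass1 (1.41, adjusted p = 0.167 over all probe sets) and Prodh, proline dehydrogenase (1.15, adjusted p = 0.206). In the plasma protein list 3 genes were lower in that way, among them the complement components C8b (-3.09, adjusted p = 0.0757) and C9 (-2.57, adjusted p = 0.193). The fetal and neonatal liver list had a mean of 0.41 (adjusted p = 0.552) with 3 genes higher adjusted over the list alone, among them Bex1 (5.34, adjusted p = 0.151) and Gpc3, glypican 3 (1.61, adjusted p = 0.284). Clock genes had a mean of 0.15 (adjusted p = 0.473), with Arntl at 2.15 (adjusted p = 0.249) and Dbp, an output gene of the clock, at -2.55 (adjusted p = 0.292). Liver transcription factors and nuclear receptors had -0.29 (adjusted p = 0.301).

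Markers of other cell types gave no call either. The mean was -0.21 for macrophages and Kupffer cells (adjusted p = 0.121), -0.41 for neutrophils (adjusted p = 0.195), -0.40 for T and natural killer cells (adjusted p = 0.316), -0.54 for B and plasma cells (adjusted p = 0.0696) and -0.47 for erythroid cells (adjusted p = 0.316). It was 0.20 for cholangiocytes and progenitors (adjusted p = 0.508), -0.13 for liver endothelium (adjusted p = 0.702), 0.45 for pancreatic acinar cells (adjusted p = 0.467), 0.11 for skeletal muscle (adjusted p = 0.780) and -1.28 for 5 adipocyte markers (adjusted p = 0.508). The adipocyte mean rests on the carbonic anhydrase Car3, which liver also makes, at -7.35 (adjusted p = 0.203). With group means below background raised to it, the mean was -0.03 for neutrophils, -0.02 for T and natural killer cells, -0.28 for B and plasma cells, 0.21 for acinar cells and 0.44 for skeletal muscle. Stress lists had means of 0.23 for p53 targets (adjusted p = 0.628), -0.12 for ATF4 and endoplasmic reticulum stress (adjusted p = 0.168), 0.33 for NRF2 and oxidative stress (adjusted p = 0.625), 0.25 for apoptosis (adjusted p = 0.372) and -0.24 for heat shock (adjusted p = 0.508). The p53 target Ddit4, an inhibitor of mTORC1 signalling, had 2.20 (adjusted p = 0.0901). Among these lists, 4 passed when the 3' over 5' index was a covariate, a setting chosen after seeing the data. Their means were then 0.51 for urea cycle and amino acid catabolism (camera adjusted p = 9.06e-06), 0.61 for liver endothelium (7.79e-05), 0.40 for pericentral genes (0.0154) and -0.18 for ATF4 and endoplasmic reticulum stress (0.0111).

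The tests in the paragraphs that follow were chosen after the result was seen, except the count of other splits. For the genes past the threshold, 15 in the real grouping, the highest of the other 9 groupings was 0, and 1 of 10 splits gave as many. For the lists, 12 in the real grouping, the highest other was 18, and 7 of 10 splits gave as many. With 10 splits no share under 0.05 is possible. The other splits called between 8 and 18 lists. Each of them still sets 2 arrays of a group against 1, so it carries part of the difference between the groups and is not a grouping without change.

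RNA quality is a candidate explanation for part of the list results, since the 3' to 5' ratios were highest in mutants 1 and 3. The ribosomal protein list is in line with it: with the 3' over 5' index as a covariate its mean went from 0.733 to -0.0362, and it was 0.10 in mutant 2, the mutant with ratios near the controls. The lower S phase, cholesterol and male-biased lists argue against RNA quality as their whole cause, because with the covariate the largest of their 3 adjusted camera p was 3.13e-12, and in mutant 2 alone their shifts were -1.50, -1.73 and -2.67. That p uses the preset correlation, and the index partly follows the groups, so a share of these shifts may still come from RNA quality. An effect of the Srf genotype on the ribosomal list stays open, as the covariate would remove it too.

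The array labelled mutant 2 lay closer to the controls than the other mutants, with Srf in the control range on 1 probe set. Against each pair of controls, its smallest shift over the S phase and cholesterol lists was 1.41 in size, where no left-out control exceeded 0.54. These lists were picked after their values in mutant 2 had been seen, from a fit that included it. A large shift there was thus partly built in. With any 1 array left out the lists still passed camera with the preset correlation (largest adjusted p = 4.28e-16 and 5.31e-17). In these lists mutant 2 lay apart from the controls, but lists so picked cannot decide whether it is a control liver. The bar was a lead over the largest left-out control greater than the range of the left-out controls' sizes, with signs ignored. A range with signs kept would be wider and the bar higher. Of the 41 lists 10 met the bar as set, while the male-biased list did not (2.21 against 1.57). This test was set after the list values of each array had been seen, but not the count of lists meeting the bar. It replaced a first test without such a bar (81.9% of 310 genes beyond all controls). It also replaced one on the 310 genes with the smallest p between mutants 1 and 3 and 2 controls (23, 13 and 40 of them past the threshold). There 85.2%, 86.1% and 91.0% lay beyond these controls in mutant 2 and 25.5%, 38.4% and 69.0% in the left-out control, short of the bar. Less complete loss of Srf, more RNA from unaffected cells and better RNA in mutant 2 were not separated by any test and stay open.

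The male-biased list was lower in all 3 mutants and also spread between the controls, where the female-biased list ran the opposite way (-0.62, 0.04 and 0.57). A first hypothesis was that the mutants may lie further along an axis that also separates the control mice, such as maturation. Across 13104 genes outside the sex-biased lists, which are not independent replicates, the rank correlations for the 3 choices of baseline control were 0.119, 0.168 and 0.0621, and the lowest reached neither the 0.1 set for this axis nor 0. A second was lower growth hormone signalling, which would lower its response genes Igf1, Igfals, Socs2 and Cish (the last pair named after their values were seen). Socs2 had 1.15 (SE 0.57, adjusted p = 0.390) and Cish -0.13 beside the negative values of Igf1 and Igfals; a rise of Socs2 above its SE was first set as the value against the hypothesis, and this was changed to the adjusted threshold after the value was seen, because a rise of 1 SE is common by chance. The question stays open.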
